A study of Mus musculus with 4 samples.

How the data were processed

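The series describes H3K27ac HiChIP, an assay that enriches proximity-ligated chromatin fragments for the acetylated histone mark of active promoters and enhancers. Sequenced read pairs report regions that lie close together in the nucleus, and are enriched for pairs in which at least 1 region is marked. The sample titles call the 4 mouse libraries ChIP-seq, whereas the extraction protocol names a micrococcal nuclease HiChIP kit and the series design names HiChIP, which is followed here because the list holds pairs of anchors. The libraries were 2 from cultured wild-type neural stem cells and 2 from YAP-M tumor. YAP-M is the study's name for a fusion of YAP1 with MAMLD1.

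The deposited positions form 1 list of 99041 interactions, which the authors' file name calls significant. Per the file header, it holds only the chromosome, start and end of the 2 anchors of each interaction, with no read count, score or q-value and no column for a sample. Per the submitters' processing notes, BWA and the mm10 genome build were used. The interaction caller, its threshold, the use of an independent peak set and the pooling of replicates are not given in the sources used here. The name of the list carries the letters YM, which are read here as the YAP-M fusion; neither the labels nor the header ties the list to particular libraries. Sequencing depth is unknown, because the list carries no counts. All anchors were 10 kb bins on the 19 autosomes, and the distances between bin starts ran from 20 to 1000 kb.

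No list for the neural stem cells was used here, so the comparison of tumor with neural stem cells was not made. The planned comparison of interaction strength between classes, and the alternatives with a stricter threshold, could not be computed from a list without counts or scores. Because there is 1 list, no value carries a replicate error and no test across libraries was run. Exact (Clopper-Pearson) 95% intervals are given for shares. They cover counting error only, and neighbouring interactions are not independent, so they are too narrow as a measure of uncertainty.

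Gene positions came from the NCBI RefSeq annotation of GRCm38.p6, the same assembly as mm10, as a table with a chromosome, start and end but no strand. A transcription start site therefore could not be told from the opposite end of a gene. In place of the planned promoter windows, both ends of each gene were used: an anchor was at a gene end if its bin overlapped a window of 2.5 kb to either side of the lowest or highest coordinate of a gene. For a gene spanning several bins, 1 of the 2 ends is not the promoter. The number of interactions of a gene is the number of distinct interactions with an anchor at either end, so a bin that holds the ends of several genes counts for each of them. There were 20665 autosomal protein-coding genes.

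The share of anchors at gene ends, and the classes of interactions, were set beside 1000 circular shifts of all anchors along each chromosome by a random offset of at least 2 Mb, with a one-sided permutation p. The 17 gene lists were fixed before the data were examined, the YAP/TEAD targets after a published signature as recalled and the others from textbook knowledge of the Hippo pathway, neural development, ependymal cells, proliferation, extracellular matrix and the other cell types a brain tumor can hold. They named 278 genes, of which 5 stood in more than 1 list (Lats2, Amotl1, Hes1, Hes5 and Sox9), 8 lay on chromosome X and could not be scored, and 1 was found through a synonym. For each list, the share of genes with an interaction and the median number of interactions per gene were placed among 10000 random lists of the same size, matched on the number of coding genes within 500 kb in 10 classes. A percentile describes where a list stands in this one interaction list; it is not a p-value, since genes are not replicates. Anchors with many interactions were set beside 1000 random reassignments of the interactions of each chromosome to pairs of observed anchors at the same distances.

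The named genes were fixed by rule before the data were examined: 15 genes named in advance (among them Yap1, Mamld1, the 4 Tead genes, Ccn1, Ccn2, Ankrd1, Sox2, Nes, Foxj1, Myc and Ccnd1), the 3 genes with the most interactions in each list (Tbr1 and Ckm, tied with these, were named after their values were seen), and the genes at the 10 anchors with the most interactions. Not every gene the rule takes is described. Any other gene named is said to have been chosen after its values were seen.

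Alternatives fixed in advance were gene-end windows of 0 and 5 kb, all annotated genes in place of coding genes, the anchor midpoint in place of any overlap, merging of interactions whose anchors lay within 1 bin of each other at both sides, a limit of 20 kb to 1 Mb, random lists without matching, and random lists drawn from genes with an interaction. Added after the data were seen were the whole gene span in place of the ends, coding genes of at most 10 kb, matching on gene length as well, random lists without olfactory and vomeronasal receptor genes, and only genes whose end bins held no end of another coding gene. The procedures were also run on simulated data. With gene counts shuffled over the 20665 genes, 7 of 100 unchanged lists of 20 genes fell outside the central 95% of random lists. Of these, 1 lay above and 6 below, against a nominal 2.5% on each side. Of 100 lists whose counts were multiplied by 2 and raised by 1, 50 lay above that range. Of 100 lists whose counts were multiplied by 3 and raised by 2, 71 did. Because of the added constant, these rates do not describe a plain 2-fold or 3-fold rise. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.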

Results

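The data consisted of a genome-wide list of chromatin interactions from H3K27ac HiChIP, read here from its name as that of YAP-M tumor, a mouse brain tumor that carries a fusion of the transcriptional co-activator YAP1 with MAMLD1. The labels describe 2 libraries of YAP-M tumor and 2 libraries of cultured mouse neural stem cells. The deposited list held 99041 interactions between 56427 distinct anchors of 10 kb, all within a chromosome, and named no library. Its read depth is unknown, and no spread between replicates could be computed. All coordinates are of mm10. The design also implies a comparison of tumor with neural stem cells, for which no interaction list was used here.

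The first question was where the listed interactions lay. The median distance between anchors was 180 kb, with an interquartile range of 100 to 300 kb. Interactions were most frequent at 100 kb (3880 interactions), 22.4% spanned less than 100 kb and 9.11% more than 500 kb. Chromosome 19 was the most densely connected autosome, with 57.0 interactions per Mb, followed by chromosome 11 with 55.7, and chromosome 14 was the sparsest with 33.2. Across the 19 autosomes, the density of interactions increased with the density of coding genes (Pearson r = 0.620, permutation p = 0.005; Spearman rho = 0.579, permutation p = 0.011; 1 relation computed, 100000 resamples, two-sided). Without chromosomes 7 and 11, the farthest from the median in gene density, r was 0.661. No interaction was listed on chromosomes X or Y, so Mamld1, which lies on X, could not be assessed.

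**Figure D1:**
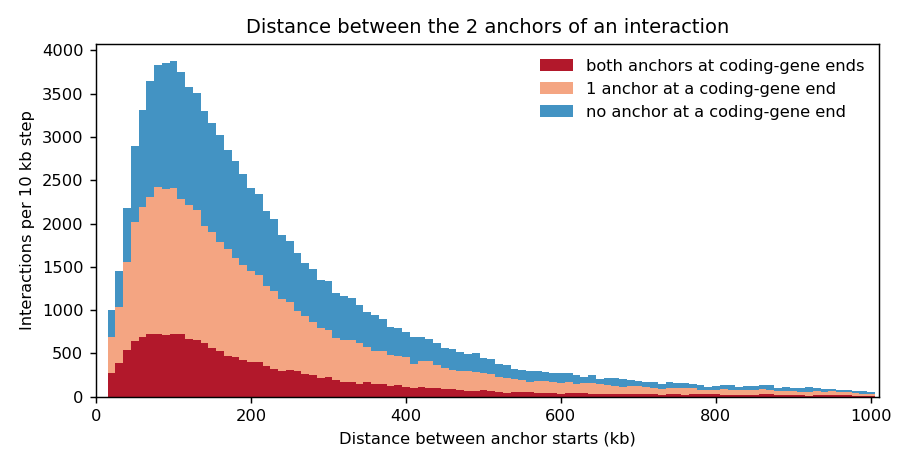
Number of interactions (y axis) at each distance between anchor starts (x axis, kb), stacked by whether both, 1 or neither of the anchors lay at an end of a coding gene. Counts peak at 100 kb, and the 3 classes follow similar distance profiles.

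Ends of protein-coding genes were over-represented among the anchors. Of the 56427 anchors, 18617 (33.0%, exact 95% interval 32.6 to 33.4%) lay at a coding-gene end, against a mean of 17.7% for shifted anchors, a ratio of 1.87. None of the 1000 shifts reached more than 18.8% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). A further 34.4% of anchors lay inside a gene away from its ends, and 32.6% lay between coding genes. Anchors at gene ends had a mean of 4.22 interactions, against 2.87 inside genes and 3.46 between genes. Interactions that joined 2 coding-gene ends made up 18.1% of the list (17906 interactions), and 5.85% after shifting. Another 43.3% joined a gene end to a site away from gene ends (23.7% after shifting), and 38.7% had no anchor at a coding-gene end (70.5% after shifting). Their median distances were 160, 180 and 180 kb. At 13580 of 20665 coding genes (65.7%), at least 1 interaction touched a gene end, with a median of 2 and an upper quartile of 7 interactions per gene.

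The second question was which genes of the pathways and cell types expected in this tumor were connected. Canonical YAP/TEAD target genes had the highest median of the lists in the main setting, though not the highest share or mean. Of 22, 21 had an interaction (95.5%, exact 95% interval 77.2 to 99.9%). Their median was 10 interactions per gene, against a mean of 2.66 and a central 95% range of 0 to 6 for the medians of matched random lists (percentile 99.97). The first rank depended on the setting. With a window of 5 kb the AP-1 median was 13.5 against 12, and after merging the cell cycle list tied at 3.5. For genes alone in their bins, the astrocyte (18), AP-1 (15), co-activator (13, a single gene) and cell cycle (10.5) medians exceeded that of the targets (10). Among the list genes named in this section, Tgfb2, Ankrd1, Tead2, Tead3, Maml2, Jag1, Nes, Polr2a, Crebbp, Thbs1, Fn1, Slc17a7, Dnaic1, Foxj1, Myrf, Cnp, Flt1, Acta2, Foxc1, Tbp, Sdha, Tbr1 and Ckm had end bins that also held an end of another coding gene, besides those said below, so their counts are shared. Tgfb2, a TGF-beta ligand, had 33 interactions, F3, the coagulation tissue factor, had 27, and Fjx1, a secreted regulator of Fat signalling, had 24. After merging of adjacent interactions, these genes had 11, 2 and 10 contacts. Among the targets used most often as reporters of YAP activity, the matricellular genes Ccn1 and Ccn2 had 21 and 13 interactions and Ankrd1 had 17. The partners of Ccn2 all lay at lower coordinates and reached 230 kb, whereas 14 of the 15 partner bins of Ccn1 lay at higher coordinates and 2 other coding genes, Bcl10 and Ddah1, had an end among them. Rbms3 was the target without an interaction at an end, a gene chosen after its value was seen. Drawn only from genes with at least 1 interaction, random lists had lower medians as well, and the targets remained at percentile 99.37.

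**Figure D2:**
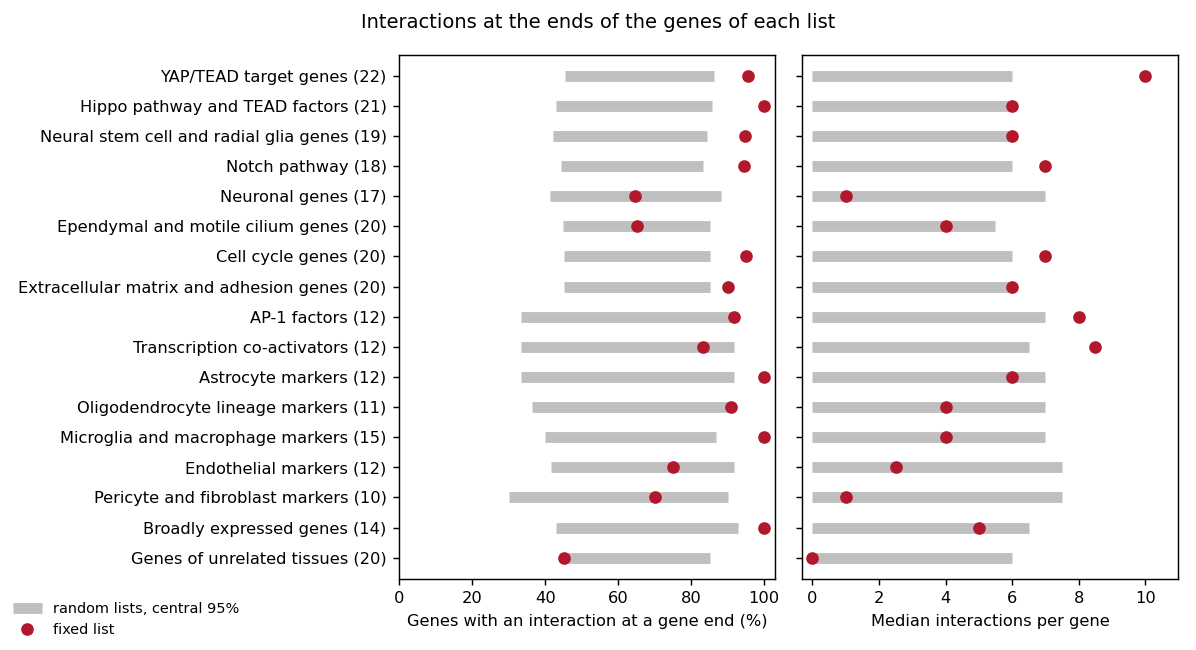
For each of the 17 gene lists (scored genes in parentheses), the left panel plots the percentage of genes with an interaction at a gene end and the right panel the median number of interactions per gene. Red points are the lists and grey bars span the central 95% of 10000 matched random lists; the YAP/TEAD targets, with a median of 10, lie farthest to the right.

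All 21 scored members of the Hippo pathway had an interaction, with a median of 6 (percentile 97.38, inside the central 95% of random lists). The counts were uneven among the TEAD factors, the DNA-binding partners of YAP. Tead1 had 28 interactions, all at its low-coordinate end, and 79 over its whole span, whereas Tead4 had 4, Tead3 had 2 and Tead2 had 1. Yap1 itself had 3 interactions, all with bins inside the gene and within 50 kb. Fat1, an atypical cadherin upstream of the pathway, had 30 interactions reaching 910 kb, and the kinase gene Map4k4 had 23.

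Genes of the Notch pathway had interactions at 17 of 18 and a median of 7 (percentile 98.98). That median lay inside the range of random lists after merging of adjacent interactions (92.59), among genes with an interaction (91.78) and for genes alone in their bins (94.46). Maml2, which encodes a mastermind-family co-activator of Notch, had 56 interactions at its ends and 168 over its span, the ligand gene Jag1 had 51, and the effector gene Hes1 had 50. Hes1 also led the neural stem cell and radial glia list, of which 18 of 19 genes had an interaction, with a median of 6 (percentile 97.04, inside the range). In that list Sox2, a transcription factor of neural progenitors, had 27 interactions. They reached 850 kb, and none of the 23 partner bins held an end of another coding gene. With 0 other coding genes within 500 kb of Sox2, the nearer bins could hardly have held one. Vim, the intermediate filament vimentin, had 26 interactions and Nes, encoding nestin, had 7. Merged into contacts, these were 2 at Vim and 4 at Nes, against 10 at Sox2. Astrocyte markers had an interaction at 12 of 12 genes with a median of 6 (percentile 95.24), led by Sox9 with 22, Gja1 with 21 and Nfia with 18. Nfia had 155 over its whole span.

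By number of interactions, proliferation and AP-1 genes included the most connected members of any list. Cell cycle genes had an interaction at 19 of 20 genes and a median of 7 (percentile 99.14). Myc had 104 interactions, and the cyclin genes Ccnd1 and Ccnd2 had 63 and 34; the bins of Ccnd1 also held an end of LTO1. Of the AP-1 factors, 11 of 12 had an interaction, with a median of 8 (percentile 99.17). Jun had 90 and Fosl2 had 71, and Batf3 had 16, including contacts with an end of Atf3, another factor of the family. Many of these interactions were adjacent. After merging, Myc had 22 contacts, but Jun, Fosl2 and Ccnd1 had 4 each, whereas Jag1 had 16 and Fat1 had 14. Transcription co-activators had a median of 8.5 (percentile 99.42) with interactions at 10 of 12. Polr2a, the largest subunit of RNA polymerase II, had 21, and the acetyltransferase genes Crebbp and Ep300 had 14 and 13. Extracellular matrix and adhesion genes had interactions at 18 of 20 and a median of 6 (percentile 97.23, inside the range), with 84 at Thbs1, 42 at Fn1 and 37 at Timp3. Against random lists drawn only from genes with an interaction, the cell cycle, AP-1 and co-activator medians lay inside the central 95%, at percentiles 92.57, 89.80 and 97.49. So did the AP-1 and co-activator medians after merging (89.17 and 96.33), the cell cycle and AP-1 medians over the whole gene span (94.26 and 96.93), and the co-activator median for genes alone in their bins (93.58, a single gene).

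Ependymal and motile cilium genes stood near random lists. Of 20, 13 had an interaction (65.0%), with a median of 4 (percentile 86.96). Cfap126 had 19, in bins shared with an end of Sdhc, Tmem212 had 13 and Dnaic1, an axonemal dynein gene, had 11. Foxj1, the regulator of motile ciliogenesis, had 9. Neuronal genes also stood inside the range of random lists: 11 of 17 had an interaction (percentile 47.49 for the share), and the median was 1 (percentile 19.62). The highest counts in that list were 5 at Slc17a7 and 4 each at Eomes, Neurog2 and Tbr1. Against genes with an interaction, the neuronal median lay at percentile 1.94.

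Markers of other cell types varied. All 15 microglia and macrophage markers had an interaction (100%, exact 95% interval 78.2 to 100%; percentile 99.93 for the share), but their median of 4 was inside the range of random lists (percentile 79.94). Itgam had 16 and Spi1 had 8, each in bins shared with an end of another coding gene. Oligodendrocyte lineage markers had interactions at 10 of 11 with a median of 4 (percentile 81.51), and Pdgfra, the receptor of oligodendrocyte progenitors, had 29, Myrf had 15 and Cnp had 9. Endothelial markers had interactions at 9 of 12 with a median of 2.5 (percentile 48.41), led by Kdr with 13, Flt1 with 10 and Pecam1 with 7. Pericyte and fibroblast markers had a median of 1 (percentile 23.80) with interactions at 7 of 10, among them Acta2 with 28, Foxc1 with 24 and Kcnj8 with 6. Broadly expressed genes had interactions at 14 of 14 and a median of 5 (percentile 91.31), with 10 at Tbp and 9 each at Sdha and Ywhaz. Genes of unrelated tissues, such as those of liver and muscle, had interactions at 9 of 20 and a median of 0 (percentile 2.26). The highest counts there were at Prm2 with 16, in bins that also held an end of Socs1, at Cela1 with 13, in bins shared with Bin2 and Galnt6, and at Apoa1, in bins shared with Sik3, and Ckm with 6 each. The percentile of that median moved inside the central 95% of random lists under 5 of the 9 alternatives (4.01 to 27.28). In all, 5 of the 17 medians lay above and 1 below the central 95% of random lists by percentile. Independent random draws of coding genes would place 0.85 outside. The fixed lists share genes and were drawn up by function, so 0.85 is not a chance level for them. The 1 below, of unrelated tissues, was 0 and equalled the lower bound of its random range (0 to 6). Of the 6 medians outside, only that of the YAP/TEAD targets stayed outside under all 9 alternatives. By share, 10 of the 17 lists lay above the central 95% by percentile and 0 below. Among them were the Hippo (percentile 99.98), astrocyte (99.76) and broadly expressed (99.87) lists, so the microglia share was not particular to that list. The AP-1 share (91.67%, percentile 97.52) equalled the upper bound of its random range. With a gene-end window of 0 kb the microglia share lay inside the range (97.27).

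The third question was which sites had the most partners. Interactions were concentrated on few anchors: 38.0% of anchors had 1 interaction, whereas the 564 anchors of the top 1% took part in 15.8% of all interactions. The largest number was 86, at the anchor on chromosome 15 from 61980001 to 61990000 that holds the low-coordinate end of Myc. In 1000 random reassignments at the same distances, no anchor exceeded 22. In the list, 392 anchors did, and 52.6% of these lay at coding-gene ends. The reassignments did not keep adjacent interactions together, whereas only 10.1% of listed interactions had no adjacent interaction. Adjacent calls can therefore raise the listed counts but not the reassigned ones. Merged contacts reached at most 24 at an anchor, and no reassignment of merged contacts was run, so the size of the excess cannot be read from this comparison. Each of the 10 anchors with the most interactions lay at an end of a coding gene. After Myc came anchors at Jun (84 interactions), Bcl6 (83), Cited2 (82), Zeb2 (74), Nrp1 (67), Sox4 (66), Enc1 (63), Klf6 (62) and again Bcl6 (60). As background, Jun and Klf6 encode transcription factors, Bcl6 and Zeb2 repressors, Cited2 a co-regulator of CBP and p300, and Sox4 a factor of neural progenitors. Nrp1 encodes the semaphorin and VEGF co-receptor neuropilin 1.

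**Figure D3:**
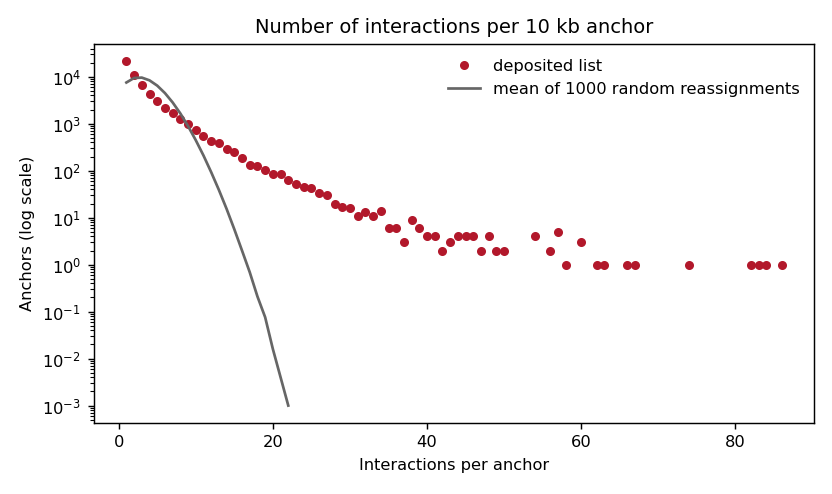
Number of anchors (y axis, log scale) by their number of interactions (x axis). Red points are the deposited list, which extends to 86 interactions. The grey line is the mean of 1000 random reassignments at the same distances, which never exceeded 22 and did not keep adjacent interactions together.

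The contacts of these anchors were mostly one-sided. The Jun anchor had 83 of its 84 partners at higher coordinates, reaching 910 kb, and the partners of Jun included an end of Fggy and of Hook1. The Bcl6 anchor at 23980001 to 23990000 on chromosome 16 had all 83 at higher coordinates, in 83 of the 99 bins that the distance limits allow on that side, and reached 1000 kb; an end of Lpp was among the partners of Bcl6. Cited2 had 80 of 82 partners at lower coordinates, Zeb2 68 of 74 at higher coordinates, Nrp1 62 of 67 at lower coordinates, and Enc1 all 63 at higher coordinates. Myc had partners on both sides, 20 lower and 66 higher, reaching 880 and 980 kb. None of its partner bins held an end of another coding gene, but none could have. Myc was the only coding gene mapped within 1 Mb of the anchor. Sox4 (42 lower, 24 higher) and Klf6 (36 lower, 26 higher) were more evenly placed. When adjacent interactions were merged into single contacts, the Klf6 anchor had 24, Myc 22, Zeb2 15, Cited2 and Sox4 13 each, and Nrp1 11. Enc1 had 6, Jun had 4, the second Bcl6 anchor had 3 and the anchor inside Bcl6 had 1, against a median of 1 over all anchors. The order among anchors thus depended on merging, and 3 of the 10 anchors were among the top 10 by merged contacts.

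**Figure D4:**
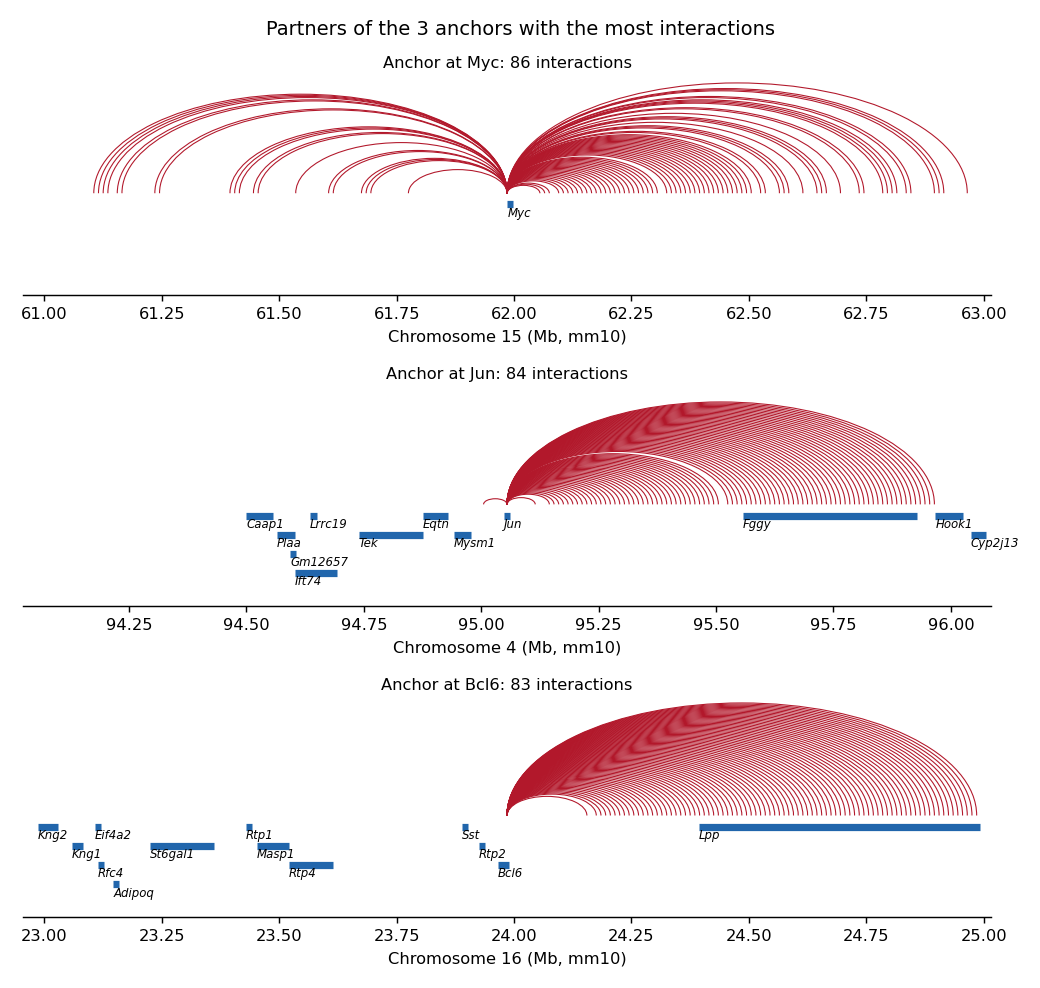
Arcs join the 3 anchors with the most interactions, at Myc (86), Jun (84) and Bcl6 (83), to the centres of their partner bins along the chromosome (x axis, Mb, mm10); arc height has no unit beyond distance. Blue bars are protein-coding genes, with short genes widened to remain visible, and show that Jun and Bcl6 contacts run almost wholly to higher coordinates.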

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

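No paired analysis was possible because the list holds no values per library. The stricter thresholds, the strength of interactions and the comparison with neural stem cells were not run, since the list has no scores and names no library. The limit of 20 kb to 1 Mb removed no interaction and so tests nothing. Depth is unknown, so a gene without an interaction was not detected at this depth rather than shown to have none. Merging adjacent interactions left 28050 contacts and lowered the largest number at an anchor to 24. Anchors at coding-gene ends were 25.5% with a window of 0 kb, 38.6% with 5 kb and 14.7% by midpoint, 49.0% for all annotated genes, 67.4% over the whole gene span and 8.42% for genes of at most 10 kb; the ratio to shifted anchors stayed between 1.37 and 2.02. Interactions with both, 1 and no anchor at gene ends were 12.3%, 40.6% and 47.1% with 0 kb, 22.6%, 44.0% and 33.4% with 5 kb, and 30.7%, 39.3% and 30.1% after merging. Of 51 list shares under another window or the gene span, 3 left the interval of the main value. Over all lists and alternatives, 28 list percentiles crossed into or out of the central 95% of random lists. The YAP/TEAD targets were the only list above it in the main setting and all 9 alternatives. The Hippo list moved above it with 0 kb (98.03), without matching (97.79) and over the gene span (99.80), the neural stem cell list with 5 kb (98.61) and with length matched (98.94), and the extracellular matrix list with 5 kb (99.18), without matching (97.99), among genes with an interaction (98.43), over the span (99.99) and for genes alone in their bins (97.67), as did the astrocyte markers in the last setting (99.15). The Notch list moved inside after merging (92.59), among genes with an interaction (91.78) and for genes alone in their bins (94.46), the cell cycle list among genes with an interaction (92.57) and over the span (94.26), the AP-1 list after merging (89.17), among genes with an interaction (89.80) and over the span (96.93), and the co-activators after merging (96.33), among genes with an interaction (97.49) and alone in their bins (93.58, a single gene, Ep300). Neuronal genes moved below it among genes with an interaction (1.94). Genes of unrelated tissues moved inside with 0 kb (4.01), 5 kb (4.21), among genes with an interaction (13.22), with length matched (5.25) and alone in their bins (27.28). The cause of each move was not tested.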

Other observations

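The tests of copy gain, of merged contacts and of shared bins as taken over the whole set were written before their results were seen; the gene families, the random lists without receptor families, the reading of copy gain by the range of its ratios, the tests of chromosome X and of gene-poor surroundings, and the division of the anchors into parts were chosen after values had been seen.

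Gene families, defined by their symbols and chosen after the counts had been seen, showed a wide range, and all families examined are named here. Their percentiles describe the same counts that prompted the choice and are not independent support. Of the 16 Krüppel-like factor genes, zinc finger transcription factors that respond to growth and stress signals, 15 had an interaction at an end and the median was 25.5 per gene (percentile 100 among 10000 matched random lists, and 100 among lists of genes with an interaction). Klf6 had 90, Klf4 had 64 and Klf7 had 63. Dual-specificity phosphatase genes, many of which dampen MAP kinase signalling, had a median of 6 (percentile 98.16, and 96.95 among genes with an interaction), led by Dusp4 with 77. Sox genes had interactions at 16 of 18 with a median of 5 (percentile 92.94). Hox genes had interactions at 32 of 39 and a median of 6 (percentile 99.45), which lay inside the central range among genes with an interaction (85.00). Ribosomal protein genes, a housekeeping family, had interactions at 74 of 82 and a median of 6, also at percentile 100, and at 84.57 among genes with an interaction. Forkhead, zinc finger protein, potassium channel, complex I and Id genes had medians of 3, 3, 2, 5 and 6, at percentiles 69.27, 85.22, 35.30, 97.82 and 82.94; complex I stood at 75.98 among genes with an interaction.

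Some families lay below random lists. Of 1104 olfactory receptor genes, 49 (4.44%, exact 95% interval 3.30 to 5.83%) had an interaction at an end, as did 13 of 354 vomeronasal receptor genes (3.67%), against 63.6% and 65.9% in matched random lists. Keratin genes (16 of 53) and cytochrome P450 genes (31 of 99) were less extreme (percentiles 1.40 and 0.01 for their medians). Among genes with an interaction, the olfactory receptors stayed at percentile 0.00, and the vomeronasal receptors (27.98), keratins (14.97) and cytochrome P450 genes (16.89) lay inside the central 95%. With both receptor families left out of the random lists, the mean random median for the YAP/TEAD targets went from 2.66 to 2.81, their percentile was 99.94, and no fixed list changed side by its median. By share, the AP-1 list moved inside the central 95% (94.29) and genes of unrelated tissues moved below it (0.89).

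Chromosome X carried 0 interactions. At the rate of the sparsest autosome, 33.2 per Mb on chromosome 14, the 170.7 Mb of X that hold annotated genes would carry 5664, and a count of 0 allows no more than 3. A single X copy or sparser acetylation, which would lower that count only in part, is argued against. X left out of the list during processing may explain the absence, and the labels do not record such a step.

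For the anchors with very many partners, copy gain of the surrounding region was weighed by counting interactions within 1 Mb that did not involve the anchor or its neighbours; the median over the 10 anchors was 1.06 times the chromosome mean. A median that low had been set beforehand as evidence against a gain, but the ratios ran from 0.300 to 2.58 between anchors, and without read depth a gain cannot be told apart from locally dense or sparse acetylation. One broad contact counted in many adjacent bins is argued against for the anchors at Klf6, Myc, Zeb2, Cited2, Sox4 and Nrp1, with 11 to 24 merged contacts. The median over the 10 anchors was 12 against 1 over all anchors, which by the rule set beforehand counted against it. That bar was low, since the 10 were picked for many interactions and 38.0% of all anchors had only 1. The anchor inside Bcl6 had 1 merged contact, which a single broad contact would leave as a continuous stripe. Its partners lay in 83 of the 99 bins allowed on that side, so many neighbouring contacts would also merge. The merged count therefore cannot tell these readings apart there. A single broad contact also stays open for the second Bcl6 anchor (3), Jun (4) and Enc1 (6). A further hypothesis is that gene-poor surroundings leave room for many partners: the 100 genes with the most interactions had a median of 5 coding genes within 500 kb, against 12 to 19 in the central 95% of 10000 random lists of genes with an interaction (percentile 0.00). The 10% of coding genes in the poorest surroundings held 27 of the 65 genes with 50 or more interactions and the 10% in the richest held 0, although the median was 2 in both.

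All 15 microglia and macrophage markers had an interaction at an end, and 9 of the other 16 lists also had shares above the central 95% of random lists. Another coding gene in the same bins may be the source: only 3 of the markers were alone in their bins, all 3 had an interaction, and that share stood at percentile 92.52 of random lists, inside the central 95%. The rule written beforehand would have counted this for shared bins, but 3 of 3 is the highest share possible and could not have left that range, so the explanation cannot be told apart from acetylation of the markers themselves. With a gene-end window of 0 kb, 13 of 15 had an interaction. Brain macrophages among the isolated cells remain a candidate source, which the list alone does not test.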
